A study of Mus musculus with 69 samples.

How the data were processed

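Gene expression was measured in macrophages grown from the bone marrow of C57Bl/6 mice. Per the labels, the cells were adhered to C1q, the recognition molecule of the classical complement pathway, or to human serum albumin (HSA), the control protein. Some cultures also received Mycobacterium avium, a non-tuberculous mycobacterium, at 1:500 or 1:1000 macrophages to bacteria. Others received 20 ng/ml lipopolysaccharide (LPS), the endotoxin of Gram-negative bacteria, with or without apoptotic Jurkat cells, a human T-cell leukaemia line, at 1:3. Cultures were taken at 4 h or 18 h. The series holds 69 arrays in 14 groups, with 5 arrays in each group except HSA with M. avium 1:500 at 18 h, which has 4. Per the series design text, the replicates of a group came from separate cultures. Groups and replicate numbers were taken from the sample labels. The number of arrays limits the precision of every value.

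The arrays were NimbleGen mouse 12-plex arrays with a single dye (Cy3). Per the series design text they were designed on the mm9 genome, with probes checked against human and M. avium sequence. Values are the intensity per transcript set deposited by the authors, made with RMA per the file headers and the submitters' processing notes. RMA corrects the background, equalises the distribution across arrays and summarises the probes of a set. Its software and version are not given in the sources used here. The deposited intensities are on a linear scale and were converted here to log2 with no offset. The deposited value table of the whole series was compared with the per-array values and differed by 0 for all 43242 sets, so its scale is linear and its genes were not centred. Its array medians are linear intensities, 193.2 for HSA 4 h replicate 1. Because the deposited values are RMA values only, another background correction was not run. Equalising the distributions would hide a change shared by most transcripts.

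Transcript sets were named through the accession table of a RefSeq annotation (GRCm38.p6), used for names only, since the array was designed on another build. Of the 43242 sets, 1373 matched 1 symbol, 14 matched several and 41855 matched none. Sets with several symbols were left unnamed. The named sets stand for 1283 genes. For 79 genes with several sets the set with the highest mean was used, and the mean of all sets was an alternative. This left 43152 transcripts tested. Most transcripts therefore carry no gene name here, and the named genes are a small part of each count. Mertk, Gas6, Tnf, Il6, Il10, Il12b, Il1b and Il27 were to be given whatever their p. They are not analysed here because this matching named no set for them, which does not mean that the array lacks them.

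The random probe set of each array and the vomeronasal receptor genes, which macrophages are not known to express, gave the background. No filter on dim transcripts was applied. The 95th percentile of the vomeronasal means is the background level here. Where a group's mean lay below it, the fold of a named gene is given as "at least". This is the brighter group's mean against the mean, over the dim group's arrays, of the higher of the background level and the array's own value. This rule was added after the data were seen. No fold is given where the means of both groups lay below it, and the adjusted p is that of the measured values. The fit used limma 3.58.1 in R 4.3.3 (packages data.table, version 1.17.8, and jsonlite, version 2.0.0), with plots in Python 3.11.15 and matplotlib 3.10.9. It had 14 group means in a single fit of all arrays, moderated variances, no block, and Benjamini-Hochberg adjustment over all transcripts of a comparison. A transcript with an adjusted p under 0.05 was called changed, and the tests of transcripts and lists were two-sided. Other splits of the arrays and swaps within pairs, given below, were counted on the side of the real value only. There were 10 main comparisons, with 5 secondary ones and 6 interactions.

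The groups, tests, alternatives, named-gene rule and 27 gene lists were chosen before the data were examined. Of those lists none had more than 2 members named by the matching used here, so none was tested. A further 11 lists were drawn up after the gene names were seen and before any comparison was computed. They are interferon-inducible genes, signalling and feedback regulators of inflammation, leukocyte surface receptors, lysosomal enzymes and membrane proteins, sterol and lipid metabolism, proliferation, small nucleolar RNAs and their host genes, and actin, adhesion and motility genes. The others are erythroid and stem cell markers, lymphocyte receptors and vomeronasal receptors, for cells or genes that the cultures should lack. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted within the functional and the other lists of a comparison. Counts "adjusted over the list alone" are given for the added lists too. For each main comparison the rule named the 5 largest rises and 5 largest falls among named genes past the test, and up to 3 passing members of each functional list that passed. Where no named gene passed, it named the 5 with the smallest p. Secondary comparisons and interactions had the 3 largest rises and falls. RIKEN, predicted and olfactory names were passed over.

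The 6 slides and 3 scan days were read from the deposited names of the arrays. Each slide held several groups, so the slide was also fitted as a block. Replicate numbers were taken to pair arrays where the deviations of every same-numbered pair from their group means correlated above 0.1. This held for C1q against HSA at 4 h (lowest 0.233) and 18 h (0.347), with LPS (0.464), with LPS and apoptotic cells (0.526) and with M. avium at 4 h (0.126). It also held for LPS (0.118), for M. avium 1:500 at 18 h (0.386) and for apoptotic cells (0.224), and for C1q with M. avium 1:500 against HSA with 1:1000 at 4 h (0.421) and 18 h (0.116). It did not hold for M. avium 1:500 at 4 h (0.0661), for C1q with M. avium at 18 h or for the other comparisons. Pairs mostly lie on the same slide at 4 h, so pairing and slide overlap. Signs over slides and pairs are given for genes picked by p or size of change in the same arrays. They describe those genes and are not separate support for them.

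Alternatives were a block for replicate number, slide or scan day, a fit of only the arrays compared, a filter on dim transcripts, and a mean over sets. Others were trended and robust moderation, a further quantile normalization, the series table, no arrays noted as rescanned or with background (7 arrays), and leaving out each array in turn. Leaving out the 6 arrays with an outlying correlation to their group was chosen after the data were seen. The pipeline was tested on simulated data with 200 changed transcripts of 43152 for C1q against HSA at 4 h. It recovered 2 of 67 at 1.5-fold, 21 of 67 at 2-fold and 59 of 66 at 4-fold, and called 7 of 42952 unchanged transcripts. At 18 h it recovered 1 of 67, 14 of 67 and 62 of 66, and called 3 unchanged transcripts. The simulated noise was independent between transcripts and arrays and held no slide or pair differences. The real arrays hold such differences, so these rates check the pipeline and need not hold for them.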

Results

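The 69 arrays measured transcripts in mouse bone marrow-derived macrophages adhered to the complement protein C1q or to the control protein HSA. Cultures were left without a stimulus, infected with M. avium, or given LPS with or without apoptotic Jurkat cells, and were taken at 4 h or 18 h. The random control probes had a median intensity of 35.22 across arrays (range 26.79 to 59.21). Vomeronasal receptor genes, which serve pheromone sensing and are not known from macrophages, had a 95th percentile of 7.24 on the log2 scale. Of the transcripts tested, 22905 (53.1%) lay above that level, as did 606 of the 1283 named genes. The correlation of an array with the mean of the rest of its group ranged from 0.835 to 0.990, with a median of 0.982, and no arrays held identical values. Component 1 of all arrays held 25.4% of the variance, of which 50.4% lay between slides and 34.5% between groups. Component 2 held 12.5%, of which 73.7% lay between groups. Within groups, the largest component of the deviations held 31.4% of the variance, and 75.1% of it lay between slides.

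**Figure D1:**
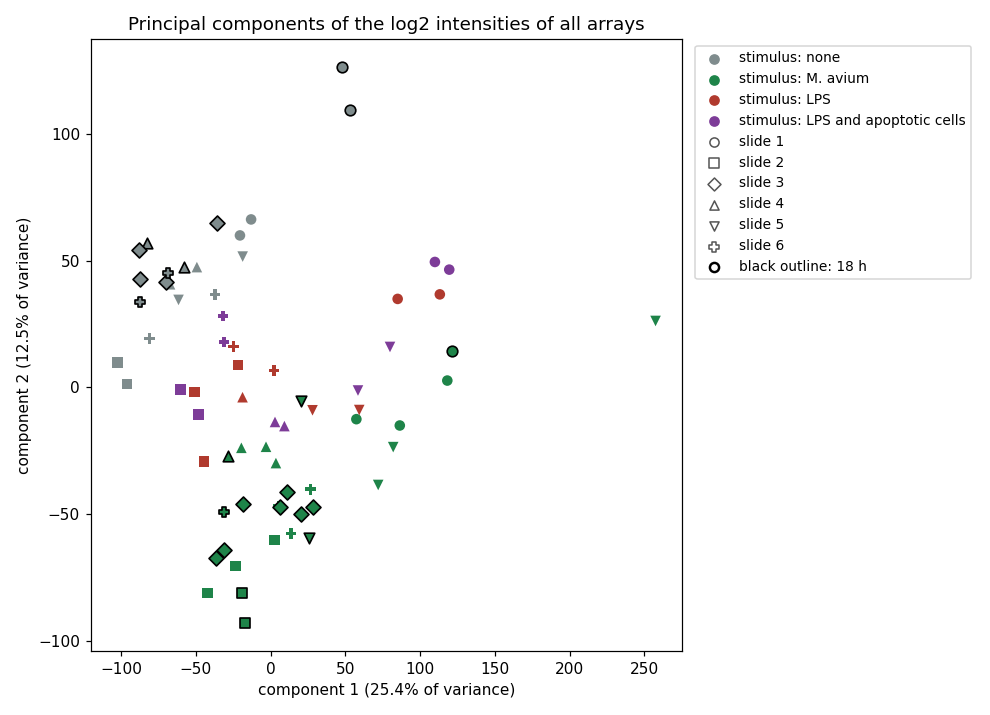
Each point is 1 of the 69 arrays, placed by its score on component 1 (25.4% of variance, x axis) and component 2 (12.5%, y axis) of the log2 intensities, with colour for the stimulus, shape for the slide and a black outline for 18 h. Arrays of slide 1 lie to the right of most arrays with the same stimulus, unstimulated arrays lie above 0 on component 2 and M. avium arrays mostly below 0, and 1 array of HSA with M. avium 1:1000 at 4 h lies far to the right.

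Adhesion to C1q for 4 h was compared with HSA to find what C1q alone changes in macrophages. Dusp5, a nuclear phosphatase that inactivates ERK kinases, was 3.57-fold lower on C1q, at 9.78 ± 0.166 against 11.62 ± 0.142 log2 units (SD, n = 5 each; log2 fold change -1.84, SE 0.258, adjusted p = 6.53e-05). Trmt61a, the catalytic subunit of a tRNA methyltransferase, fell by 1.39 on the log2 scale (SE 0.279, adjusted p = 0.00717). Purg, a purine-rich element binding protein, rose at least 1.32-fold (adjusted p = 0.00229), above the background level on 4 of 5 C1q arrays and 0 of 5 HSA arrays. Arl5c, a small GTPase of the ARF-like family, rose by 1.38 (SE 0.315, adjusted p = 0.0256), and Rere, a nuclear corepressor, by 0.82 (SE 0.200, adjusted p = 0.0453). Each of these genes moved the same way on 5 of 5 slides and in 5 of 5 pairs. Of the 10 interferon-inducible genes, none passed on its own over all transcripts (0 rose, 0 fell, 10 not passing), and 2 passed when adjusted over the list alone. Their median was 0.27 (camera adjusted p = 0.000851), with adjusted p = 0.545 with an estimated correlation. The 99 vomeronasal receptors also had a median of 0.27. The remaining functional lists did not pass, with camera adjusted p of 0.185 for small nucleolar RNAs and their host genes, 0.297 for signalling regulators, 0.323 for lysosomal genes and 0.438 for actin and adhesion genes. The values were 0.792 for leukocyte receptors, 0.876 for proliferation, where the median (0.05) was above 0 and the test pointed down, and 0.974 for sterol and lipid genes. Of the signalling regulators Dusp5 fell, 0 rose and 11 did not pass (1 when adjusted over the list alone). Erythroid and lymphocyte markers had no passing member (camera adjusted p = 0.624 for both lists).

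With limma, 123 transcripts changed between C1q and HSA at 4 h, of which 51 rose and 72 fell, and 98 changed at least 2-fold. With the slide as a block 674 changed and with the replicate number as a block 415, and all 123 were called in either fit. In a fit of only these arrays 6 changed, Dusp5 and Trmt61a among the genes kept and Arl5c, Purg and Rere not. The count was 67 without HSA replicate 4, 59 without HSA replicate 5, and 61, 77 and 76 without C1q replicates 1, 3 and 4. Arl5c was not called without HSA replicates 1, 4 or 5 or C1q replicates 1, 2 or 3 (adjusted p up to 0.133), and Rere kept its call only without HSA replicates 1 or 3 or C1q replicate 2 (up to 0.238).

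At 18 h, interferon-inducible genes were higher on C1q than on HSA and several genes of cell division were lower. Ifit1bl1, of the interferon-induced IFIT family, was 5.07-fold higher on C1q (log2 fold change 2.34, SE 0.418, adjusted p = 0.000584), at 12.10 ± 0.769 against 9.76 ± 1.42 log2 units (SD, n = 5 each). Mx1, an interferon-induced antiviral GTPase, rose by 1.44 (SE 0.356, adjusted p = 0.0236) and Irgm2, an immunity-related GTPase, by 0.86 (SE 0.223, adjusted p = 0.0345). Uhrf1, which maintains DNA methylation in dividing cells, was 3.93-fold lower (log2 fold change -1.97, SE 0.332, adjusted p = 0.000247). Dusp5 was 3.08-fold lower (-1.62, SE 0.258, adjusted p = 8.42e-05). Neil3, a DNA glycosylase, fell by 1.43 (adjusted p = 0.0311) and Ttk, a kinase of the mitotic checkpoint, was at least 1.87-fold lower (adjusted p = 0.0474). Of the C1q arrays, 3 of 5 lay above the background level for Neil3 and 1 of 5 for Ttk. Lrp8, a lipoprotein receptor, fell by 1.31 (adjusted p = 0.0431). Arl5c rose by 1.63 (adjusted p = 0.00179) and Tmem176a, a membrane protein gene, by 1.46 (adjusted p = 0.0348). The apolipoprotein gene Apoc1 passed as higher (adjusted p = 0.00446), with the means of both groups below the background level. All of these moved the same way on 4 of 4 slides and in 5 of 5 pairs.

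Of the 10 interferon-inducible genes at 18 h, 3 rose on C1q, 0 fell and 7 did not pass, and 7 passed when adjusted over the list alone. The median was 0.66 (camera adjusted p = 5.97e-15, adjusted p = 0.0120 with an estimated correlation), above 0 on 4 of 4 slides. Of 12 proliferation genes, 3 fell, 0 rose and 9 did not pass, with 3 passing when adjusted over the list alone and a median of -0.40 (camera adjusted p = 9.07e-07, adjusted p = 0.0338 with an estimated correlation). The vomeronasal receptors had a median of 0.23, with none called. Limma called 421 transcripts, 182 rising and 239 falling, against 1013 with the slide as a block and 805 with the replicate number as a block. In a fit of only these arrays 120 passed, of which 74 rose, so the balance of rises and falls turned. That fit called none of the 3 interferon-inducible genes (adjusted p = 0.170 for Ifit1bl1, 0.204 for Mx1 and 0.255 for Irgm2). Nor did it call Arl5c (0.0911), Dusp5 (0.0504), Neil3 (0.194), Ttk (0.0528) or Lrp8 (0.155). Without the arrays noted as rescanned or with background 191 passed, and Mx1 (0.111), Irgm2 (0.189), Tmem176a (0.0593), Neil3 (0.119), Ttk (0.157) and Lrp8 (0.0991) did not. Mx1, Irgm2, Tmem176a, Neil3, Ttk and Lrp8 also lost their calls without the outlying arrays (adjusted p from 0.123 for Neil3 to 0.319 for Irgm2), and Ttk with quantile normalization (0.0613). The count was 195 and 253 without HSA replicates 2 and 3, and 218, 213 and 266 without C1q replicates 1, 3 and 5. Leaving out 1 array ended several calls. That of Tmem176a held only without C1q replicate 4, that of Ttk only without C1q replicate 5, and that of Lrp8 only without HSA replicate 3 or C1q replicate 2. Irgm2 kept its call only without HSA replicates 4 or 5 or C1q replicate 2. Mx1 lost it without HSA replicates 1, 2 or 3 or C1q replicates 1, 3 or 4, and Neil3 without HSA replicates 2, 4 or 5 or C1q replicates 1 or 3. The highest adjusted p without 1 array was 0.114 for Tmem176a, 0.195 for Ttk, 0.302 for Lrp8, 0.165 for Irgm2, 0.140 for Mx1 and 0.257 for Neil3. Between the times the C1q effect differed for 0 transcripts with limma (1260 at an unadjusted p under 0.05), 4 with the replicate number and 5 with the slide as a block. For the interferon-inducible genes the difference between the times had a median of 0.41 (camera adjusted p = 0.000864, adjusted p = 0.524 with an estimated correlation).

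M. avium at 1:500 was compared with no bacteria on HSA to give the response to infection. At 4 h interferon-inducible genes rose the most among named genes. Mx1 was 14.2-fold higher, at 13.97 ± 0.241 against 10.14 ± 0.641 log2 units (SD, n = 5 each; log2 fold change 3.82, SE 0.356, adjusted p = 1.37e-12). Serpina3f, a serine protease inhibitor, rose at least 3.89-fold (adjusted p = 1.5e-07), with 0 of 5 arrays above the background level without bacteria. Ifit1bl1 rose by 3.35 (adjusted p = 8.09e-09), Isg15, a ubiquitin-like modifier, by 3.28 (adjusted p = 1.87e-10) and Irgm2 by 2.44 (adjusted p = 7.29e-13). Rasgrp3, an exchange factor for Ras, was at least 3.78-fold lower (adjusted p = 0.000346), and Pvt1, a long non-coding RNA next to Myc, fell by 2.39 (adjusted p = 3.52e-06). The receptor gene Gprc5c fell by 2.22 (adjusted p = 8.3e-05) and the zinc finger gene Zfp395 was at least 2.76-fold lower (adjusted p = 0.000219). Uhrf1 fell by 2.13 (adjusted p = 1.97e-06), Neil3 was at least 2.08-fold lower (adjusted p = 0.000254) and the cell cycle-associated gene Cdca7l fell by 1.75 (adjusted p = 0.00137). With M. avium, 1 of 5 arrays lay above the background level for Rasgrp3, 2 of 5 for Zfp395, 3 of 5 for Pvt1 and 4 of 5 for Cdca7l, and 0 of 5 for Neil3. Each moved the same way on 5 of 5 slides.

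All 10 interferon-inducible genes rose at 4 h of M. avium 1:500 (0 fell, 0 not passing, 10 when adjusted over the list alone), with a median of 2.42 (camera adjusted p = 1.28e-23, adjusted p = 0.000695 with an estimated correlation). Of the 12 proliferation genes, 8 fell and 4 did not pass (9 when adjusted over the list alone), with a median of -0.98 (camera adjusted p = 3.05e-06, adjusted p = 0.0466 with an estimated correlation). The other 6 functional lists did not pass (camera adjusted p = 0.839 for each). The leukocyte receptor median (0.08) and the lysosomal median (-0.03) had signs opposite to their tests. Nor did the erythroid and lymphocyte markers pass (0.615 for both). Vomeronasal receptors had a median of 0.34, with none called. Limma called 5277 transcripts, 2597 rising and 2680 falling, and 8381 with the slide as a block. The count was 2902 in a fit of only these arrays, where Gprc5c lost its call (adjusted p = 0.0673), and 3186 without the arrays noted as rescanned or with background. More rose than fell in those fits (1507 and 2044 rising).

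At 18 h of M. avium 1:500 the zinc finger gene Zfp811 was at least 3.39-fold higher (adjusted p = 1.94e-14), with 0 of 5 arrays above the background level without bacteria. Acp5, the tartrate-resistant acid phosphatase of osteoclasts and macrophages, was 11.2-fold higher, at 10.88 ± 0.893 (SD, n = 4) against 7.38 ± 0.752 log2 units (SD, n = 5; log2 fold change 3.49, SE 0.455, adjusted p = 2.23e-08), with 4 of 5 arrays above that level without bacteria. Ifit1bl1 rose 10.7-fold, Mx1 6.87-fold and Serpina3f at least 2.61-fold (adjusted p = 0.000803). Pcp4l1 was 16.1-fold lower (-4.01, SE 0.329, adjusted p = 9.6e-15). With M. avium, 0 of 4 arrays lay above the background level for Neil3, Gprc5c and Ttk, which were at least 2.80-fold (adjusted p = 9.01e-12), 7.03-fold (2.91e-08) and 1.88-fold lower (2.03e-07). Uhrf1 had a log2 fold change of -3.47. Rasgrp3 was at least 6.36-fold lower (adjusted p = 1.11e-05), with 1 of 4 arrays above that level. All moved the same way on 4 of 4 slides. Of the interferon-inducible genes, 8 rose, 0 fell and 2 did not pass (10 when adjusted over the list alone), with a median of 1.46 (camera adjusted p = 8.54e-16, adjusted p = 0.00448 with an estimated correlation). Of the proliferation genes, 9 fell, 0 rose and 3 did not pass (9 when adjusted over the list alone), with a median of -1.39 (camera adjusted p = 4.95e-14, adjusted p = 0.00121 with an estimated correlation). Of the 12 signalling regulators, 2 rose, 0 fell and 10 did not pass (4 when adjusted over the list alone). These were the kinase gene Pim3 (2.06, adjusted p = 4.74e-05) and Zc3h12a (1.88, adjusted p = 1.22e-09), an RNase that degrades inflammatory mRNAs. The list's camera adjusted p was 0.0301, with adjusted p = 0.167 with an estimated correlation and 0.0661 with the replicate number as a block. In the fit with that block the list's median was 0.0917. Of the 12 leukocyte receptors, 3 fell, 0 rose and 9 did not pass (5 when adjusted over the list alone). Cd59a, an inhibitor of the complement membrane attack complex, fell by 1.19 (adjusted p = 0.00376) and Cd300ld5 fell by 1.09 (adjusted p = 9.92e-06). Vsig4, a complement receptor of the immunoglobulin family, passed as lower (adjusted p = 0.00736) with the means of both groups below the background level. The leukocyte receptor list had a camera adjusted p of 0.0440, with adjusted p = 0.0511 with an estimated correlation, 0.0661 with the replicate number and 0.0958 with the slide as a block. Its median was -0.547 with the replicate number and -0.465 with the slide as a block. Without HSA M. avium 1:500 replicate 3, Cd59a was not called (adjusted p = 0.0664). Lysosomal, sterol, small nucleolar RNA and actin lists did not pass (camera adjusted p = 0.846, 0.262, 0.401 and 0.962), with a lysosomal median of -0.18 where the test pointed up, nor did erythroid and lymphocyte markers (0.611 for both). Vomeronasal receptors had a median of 0.20. Limma called 3560 transcripts, 1677 rising and 1883 falling, against 5198 with the slide as a block and 5085 with the replicate number. Without the outlying arrays 1433 of 2816 rose.

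The effect of M. avium 1:500 differed between 18 h and 4 h for 370 transcripts, 130 higher and 240 lower at 18 h. Among named genes, the difference was 2.09 for Zfp811 (SE 0.478, adjusted p = 0.0137) and 0.96 for Mocs1, of molybdenum cofactor synthesis (SE 0.244, adjusted p = 0.0319). It was -3.43 for Pcp4l1 (SE 0.452, adjusted p = 3.61e-06), -2.09 for Neil3 (SE 0.531, adjusted p = 0.0318) and -1.68 for Lnpk, a protein of the endoplasmic reticulum (SE 0.394, adjusted p = 0.0170). The values for Zfp811 and Neil3 rest on groups below the background level, with Zfp811 above it on 0 of 5 arrays without bacteria at either time and Neil3 on 0 of 5 and 0 of 4 arrays with M. avium at 4 h and 18 h. The count was 1033 with the slide and 767 with the replicate number as a block, 101 in a fit of only these arrays, where Mocs1 (adjusted p = 0.479) and Lnpk (0.194) were not called. It was 158 without the arrays noted as rescanned or with background, where Zfp811, Mocs1, Neil3 and Lnpk were not called. Mocs1 (0.0640) and Neil3 (0.0891) also lost their calls without the outlying arrays. It was 201 without HSA M. avium 1:500 18 h replicate 3. Neil3 and Lnpk were not called without that array (adjusted p = 0.117 and 0.0799). Lnpk was also not called without HSA 4 h replicate 5 (0.0657). Neil3 was also not called without HSA 4 h replicates 1 or 4, HSA M. avium 1:500 4 h replicates 1, 3 or 5, or HSA 18 h replicates 2 or 4. Mocs1 was not called without HSA 4 h replicate 5, HSA M. avium 1:500 4 h replicates 1 or 2, HSA 18 h replicates 2 or 3, or HSA M. avium 1:500 18 h replicates 1 or 4 (adjusted p up to 0.122). For the interferon-inducible genes the difference had a median of -0.94 (camera adjusted p = 0.000261, adjusted p = 0.145 with an estimated correlation), and for proliferation genes of -0.45 (0.00141, adjusted p = 0.129 with an estimated correlation). The signalling list had 0.27 (0.0104) and the sterol and lipid list -0.53 (0.0255), both with adjusted p = 0.129 with an estimated correlation.

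With M. avium at 1:1000, Mx1 and Ifit1bl1 rose at 4 h by 3.68 and 3.47 and Serpina3f at least 4.46-fold, with 0 of 5 arrays above the background level without bacteria. Uhrf1 had a log2 fold change of -2.66, Rasgrp3 was at least 4.05-fold lower and the zinc finger gene Zcchc24 at least 2.10-fold lower (adjusted p = 8.18e-05 or lower for each). With M. avium, 1 of 5 arrays lay above that level for Rasgrp3 and 0 of 5 for Zcchc24. At 18 h Acp5 was 28.8-fold higher (4.85, SE 0.429, adjusted p = 7.44e-14, 4 of 5 arrays without bacteria above the background level). Zfp811 was at least 3.33-fold (adjusted p = 1.4e-15) and Ifit1bl1 8.05-fold higher, Pcp4l1 and Uhrf1 had log2 fold changes of -4.09 and -3.82, and Rasgrp3 was at least 6.36-fold lower (adjusted p = 4.93e-08). For Zfp811 0 of 5 arrays without bacteria lay above that level, and for Rasgrp3 0 of 5 with M. avium. The interferon-inducible genes had medians of 2.62 at 4 h (9 rose, 1 not passing, 10 when adjusted over the list alone, adjusted p = 0.00628 with an estimated correlation) and 1.21 at 18 h (8 rose, 2 not passing, 8 when adjusted over the list alone, adjusted p = 0.0320). The proliferation genes had medians of -1.48 at 4 h (9 fell, 3 not passing, 9 when adjusted over the list alone, adjusted p = 0.0535 with an estimated correlation) and -1.51 at 18 h (10 fell, 2 not passing, 10 when adjusted over the list alone, 0.00113). Limma called 10678 transcripts at 4 h (4312 rising, 6366 falling) and 5728 at 18 h (2632 rising, 3096 falling), or 16101 and 7373 with the slide as a block. In a fit of only these arrays 2619 passed at 4 h. Without replicate 2 at 1:1000 the 4 h count was 6089, and this array correlated with its group at 0.835. Of the 99 vomeronasal receptors 43 were called at 4 h, with a median of 0.97, and 3 without that array, with a median of 0.51. At 18 h only 1 slide held both groups. Between 1:1000 and 1:500, 0 transcripts passed with limma at 4 h (3948 at an unadjusted p under 0.05, 1 with the slide as a block) and 0 at 18 h (1575 at an unadjusted p under 0.05, 0 with either block). Without replicate 2 the 4 h comparison of the ratios still had 0 transcripts, and 923 at an unadjusted p under 0.05.

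**Figure D2:**
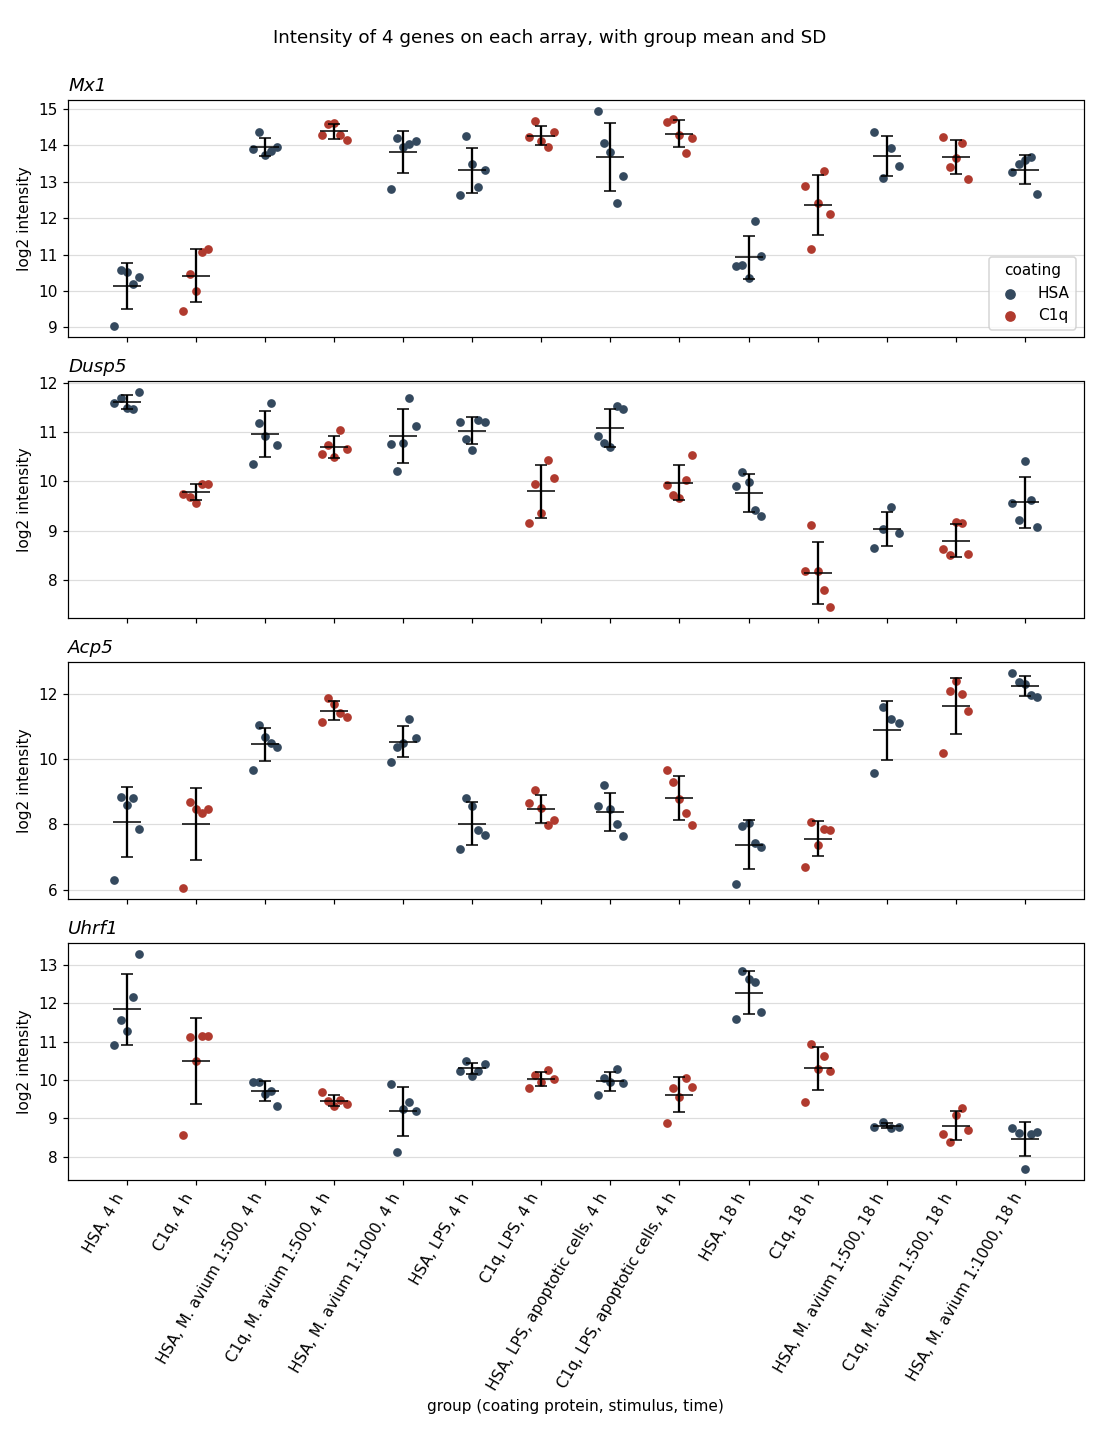
Log2 intensity (y axis) of Mx1, Dusp5, Acp5 and Uhrf1 on each array, by group (x axis), with points blue for HSA and red for C1q, a wide bar for the group mean and whiskers for the SD (n = 5, or 4 for HSA with M. avium 1:500 at 18 h). Mean Dusp5 is 9.78 on C1q against 11.62 on HSA at 4 h without a stimulus, mean Mx1 is above 13 in every group with M. avium or LPS, mean Acp5 is above 10 in the M. avium groups alone, and mean Uhrf1 is lowest in the M. avium groups at 18 h.

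C1q was compared with HSA in the presence of M. avium 1:500 to ask whether C1q alters the response to the bacteria. At 4 h no transcript passed with limma (0 called, 1597 at an unadjusted p under 0.05, smallest adjusted p 0.114), against 9 with the slide and 4 with the replicate number as a block. Named genes with the smallest p were Foxl2os (at least 1.43-fold higher, adjusted p = 0.263), Ptchd1 (-0.99, adjusted p = 0.282), Purg (at least 1.09-fold higher), Zbtb3 (0.84) and Trmt61a (-0.79), the last 3 with an adjusted p of 1. Of the HSA arrays, 0 of 5 lay above the background level for Foxl2os and Purg and 4 of 5 for Zbtb3. Each had the same sign in 5 of 5 pairs, which can follow from their choice by smallest p. Dusp5 had a log2 fold change of -0.26 (SE 0.258, adjusted p = 1). The 10 interferon-inducible genes, 0 of them passing, had a median of 0.37 (0 when adjusted over the list alone, camera adjusted p = 8.84e-05, adjusted p = 0.506 with an estimated correlation), while vomeronasal receptors had -0.06. The count was 1 without HSA M. avium 1:500 replicate 1 or replicate 3. At 18 h 0 transcripts passed with limma (1350 at an unadjusted p under 0.05, smallest adjusted p 0.163), and 5 with either block, and 1 without C1q M. avium replicate 1. Named genes with the smallest p were Col18a1, the source of endostatin (-0.93, SE 0.231, adjusted p = 0.896), Ptchd1 (-0.91), Tead3, Pinc and Myadm (-0.39), all others with an adjusted p of 1. The means of both groups lay below the background level for Tead3 and Pinc. The actin and adhesion list had a median of -0.18 with 0 of 16 genes passing (camera adjusted p = 0.0473, adjusted p = 0.520 with an estimated correlation, 0.113 with the replicate number as a block). The interferon-inducible genes had a median of -0.04 (camera adjusted p = 0.727). Only 1 slide held both groups at 18 h.

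The difference of the C1q effect between M. avium and no stimulus was tested as an interaction. At 4 h 0 transcripts passed with limma (1217 at an unadjusted p under 0.05), 5 with the slide and 2 with the replicate number as a block. Dusp5 had an interaction of 1.57 (SE 0.364, adjusted p = 0.513). At 18 h 0 passed (1555 at an unadjusted p under 0.05), 8 with the slide and 35 with the replicate number as a block, and 1, 1 and 2 without HSA replicates 4 and 5 and C1q replicate 2. The interferon-inducible genes had an interaction median of -0.79 at 18 h (0 passing, 5 when adjusted over the list alone, camera adjusted p = 2.36e-11, adjusted p = 0.0437 with an estimated correlation, fry adjusted p = 0.0647), while the vomeronasal receptors had -0.30. Only 1 slide held both M. avium groups at 18 h, and within it the list's C1q effect with M. avium had a median of -0.09. For proliferation genes it was 0.32 (0.00972, adjusted p = 0.461 with an estimated correlation). Setting C1q with M. avium 1:500 against HSA with 1:1000, 6 transcripts passed at 4 h and 4 at 18 h, among them Col18a1, named after its value was seen. These comparisons differ in bacterial dose. The 4 h count was 51 with the slide and 35 with the replicate number as a block and 0 without replicate 2 of HSA at 1:1000. It was also 0 without C1q replicates 1, 2, 3 or 4, 2 without HSA replicate 1 and 18 without HSA replicate 4. The 18 h count was 43 with the slide and 40 with the replicate number as a block. It was 0 without C1q replicate 1 or HSA replicates 1 or 2, 1 without C1q replicate 3 or HSA replicate 5, 2 without HSA replicate 3 and 14 without C1q replicate 2.

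LPS was compared with no stimulus on HSA at 4 h as the response to endotoxin. Mx1 was 9.03-fold higher, at 13.32 ± 0.628 against 10.14 ± 0.641 log2 units (SD, n = 5 each; log2 fold change 3.18, SE 0.356, adjusted p = 1.79e-09). Ifit1bl1 rose by 2.99 (adjusted p = 5.74e-07), Serpina3f at least 2.26-fold (adjusted p = 7.76e-05, 0 of 5 arrays without LPS above the background level), Ifit3b, also of the IFIT family, by 2.35 (adjusted p = 0.000129) and Isg15 by 2.19 (adjusted p = 1.83e-05). Zfp395 fell by 1.59 (adjusted p = 0.0275, 2 of 5 LPS arrays above that level), Uhrf1 fell by 1.54 (adjusted p = 0.00156), the transcription factor gene Tox2 fell by 1.49 (adjusted p = 0.00409) and the receptor gene Gpr146 fell by 1.41 (adjusted p = 0.00268). These moved the same way on 4 of 4 slides and in 5 of 5 pairs. Gprc5c fell by 1.52 (adjusted p = 0.0246), on 3 of 4 slides and in 4 of 5 pairs. Of the interferon-inducible genes 8 rose, 0 fell and 2 did not pass (10 when adjusted over the list alone), with a median of 2.18 (camera adjusted p = 1.74e-25, adjusted p = 0.000392 with an estimated correlation). Of the proliferation genes 1 fell and 11 did not pass (1 when adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.0955). Vomeronasal receptors had a median of 0.40, with none called.

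Limma called 1551 transcripts with LPS, 1137 rising and 414 falling, against 5716 with the slide and 2852 with the replicate number as a block. In a fit of only these arrays 793 passed and Uhrf1, Gprc5c and Tox2 were not called. The count was 1013 without HSA replicate 5 and 988 and 1033 without LPS replicates 2 and 3. Zfp395 was not called without HSA replicates 1, 2 or 4 or LPS replicates 2, 3 or 5 (adjusted p up to 0.102), nor Gprc5c without HSA replicates 4 or 5 or LPS replicate 3 (up to 0.304). Without the outlying arrays Zfp395 (0.0561) and Gprc5c (0.0909) were also not called. Of the transcripts raised by LPS, 1082 were also raised by M. avium 1:500 at 4 h, against 68.4 for independent lists, and 336 fell with both, against 25.7, with 0 opposed. Both comparisons use the same HSA arrays. The correlation of their fold changes across genes, which are not independent replicates, was 0.80. In 20 simulations the control, M. avium and LPS arrays were all replaced by the same means with independent noise. Those simulations gave a mean correlation of 0.50, with at most 1 transcript called in both. The covariance was 0.259, against 0.0599 in the simulations. No transcript was changed in the simulations, so few joint calls were fixed in advance. That count does not show how far shared controls add to the overlap where transcripts do change. The simulated noise also had no slide differences, so the simulated correlation and covariance show what shared controls give without them. With the controls divided between the comparisons in 10 ways, the correlation was 0.289 to 0.626 and the covariance 0.126 to 0.227. LPS then raised 303 to 3674 transcripts, 294 to 804 rose with both and 17 to 251 fell with both. Each comparison then had fewer control arrays, so these counts also reflect a less precise test.

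C1q was compared with HSA in the presence of LPS at 4 h. Dusp5 was 2.35-fold lower on C1q, at 9.80 ± 0.530 against 11.03 ± 0.268 log2 units (SD, n = 5 each; log2 fold change -1.24, SE 0.258, adjusted p = 0.0283). Rcsd1, which binds the actin-capping protein CapZ, rose by 0.84 (SE 0.172, adjusted p = 0.0270). Both moved the same way on 4 of 4 slides and in 5 of 5 pairs. Of the interferon-inducible genes 0 passed (3 when adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.6e-09, adjusted p = 0.0870 with an estimated correlation), and vomeronasal receptors had a median of 0.23. The signalling regulators had a median of -0.14, with Dusp5 falling, 0 rising and 11 not passing (1 when adjusted over the list alone, camera adjusted p = 0.00993, adjusted p = 0.134 with an estimated correlation, 0.0534 with the slide as a block). The 15 small nucleolar RNAs and host genes had a median of -0.31 with 0 passing (camera adjusted p = 0.00365, adjusted p = 0.134 with an estimated correlation). Limma called 23 transcripts, 6 rising and 17 falling, against 101 with the slide and 100 with the replicate number as a block, and 4 in a fit of only these arrays. It called 8 without the arrays noted as rescanned or with background, where Dusp5 and Rcsd1 were not called, nor were they in the fit of only these arrays (adjusted p from 0.00706 to 0.272 for Dusp5 and from 0.00694 to 0.297 for Rcsd1 over 11 alternatives). The count was 9, 52, 10 and 8 without HSA LPS replicates 1, 2, 4 and 5, and 8 without C1q LPS replicate 2 or replicate 3. Neither gene was called without HSA LPS replicates 1, 4 or 5 or C1q LPS replicates 1, 2 or 3, and Rcsd1 was also not called without C1q LPS replicate 4 (adjusted p up to 0.176 for Dusp5 and 0.167 for Rcsd1). The C1q effect differed between LPS and no stimulus for 0 transcripts with limma (1249 at an unadjusted p under 0.05, 0 with either block, 1 without HSA 4 h replicate 2 or HSA LPS replicate 2). Dusp5 had an interaction of 0.60 (SE 0.364, adjusted p = 1).

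Apoptotic Jurkat cells were added to LPS-treated macrophages on HSA to ask what apoptotic cells change. No named gene passed. Those with the smallest p were Hmgcs1, an enzyme of cholesterol synthesis (-0.77, SE 0.208, adjusted p = 0.282), Slc43a2, an amino acid transporter gene (0.80, adjusted p = 0.412), Lrp8 (1.18, SE 0.348, adjusted p = 0.463), Odf3l1 and the kinase gene Nim1k (at least 1.05-fold lower), the last 2 with adjusted p = 0.607. The means of both groups lay below the background level for Odf3l1, and 2 of 5 arrays with LPS alone and 0 of 5 with apoptotic cells lay above it for Nim1k. Each had the same sign in 5 of 5 pairs and on 4 of 4 slides, which can follow from their choice by smallest p. Lrp8 passed with the replicate number (adjusted p = 0.0369) and the slide (0.0143) as a block, within a range of 0.0143 to 1 over 11 alternatives. Sterol and lipid genes, to which Hmgcs1 and Lrp8 belong, had 0 passing (2 when adjusted over the list alone, camera adjusted p = 0.893), and the interferon-inducible genes had a median of 0.21 (camera adjusted p = 0.204). Limma called 20 transcripts, 15 rising and 5 falling, none with a name here, against 91 with the slide and 69 with the replicate number as a block. A further quantile normalization gave 46. None passed in a fit of only these arrays (0), and 3 passed without the arrays noted as rescanned or with background. The count was 1 without HSA LPS replicate 1, 2 or 3, and 2, 13, 13 and 6 without replicates 1, 2, 4 and 5 of HSA with LPS and apoptotic cells.

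With LPS and apoptotic cells together, C1q was again compared with HSA. Dusp5 had a log2 fold change of -1.11 (SE 0.258, adjusted p = 0.243, 5 of 5 pairs). It passed with the slide as a block (adjusted p = 0.0217) and not with the replicate number (0.0868), within a range of 0.0217 to 1 over 11 alternatives. Ptchd1 (-0.84, adjusted p = 0.817), Gpatch4 (-0.61), Metrnl (-0.71) and Tm6sf1 (-0.49) followed, the last 3 with an adjusted p of 1. Limma called 3 transcripts, all falling and without a name here, against 29 with the slide and 13 with the replicate number as a block. None passed in a fit of only these arrays (0), and 1 passed without the arrays noted as rescanned or with background. The count was 5 without HSA replicate 1 and 6 without C1q replicate 5. The interferon-inducible genes had a median of 0.43 with 0 passing (0 when adjusted over the list alone, camera adjusted p = 8.69e-09, adjusted p = 0.115 with an estimated correlation), while vomeronasal receptors had -0.03. The C1q effect differed between LPS with and LPS without apoptotic cells for 0 transcripts with limma (171 at an unadjusted p under 0.05, 0 with either block). For that difference, proliferation genes and small nucleolar RNAs had medians of 0.24 and 0.28 (camera adjusted p = 0.0397 for both, adjusted p = 0.508 with an estimated correlation, 0.169 and 0.179 with the slide as a block).

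**Figure D3:**
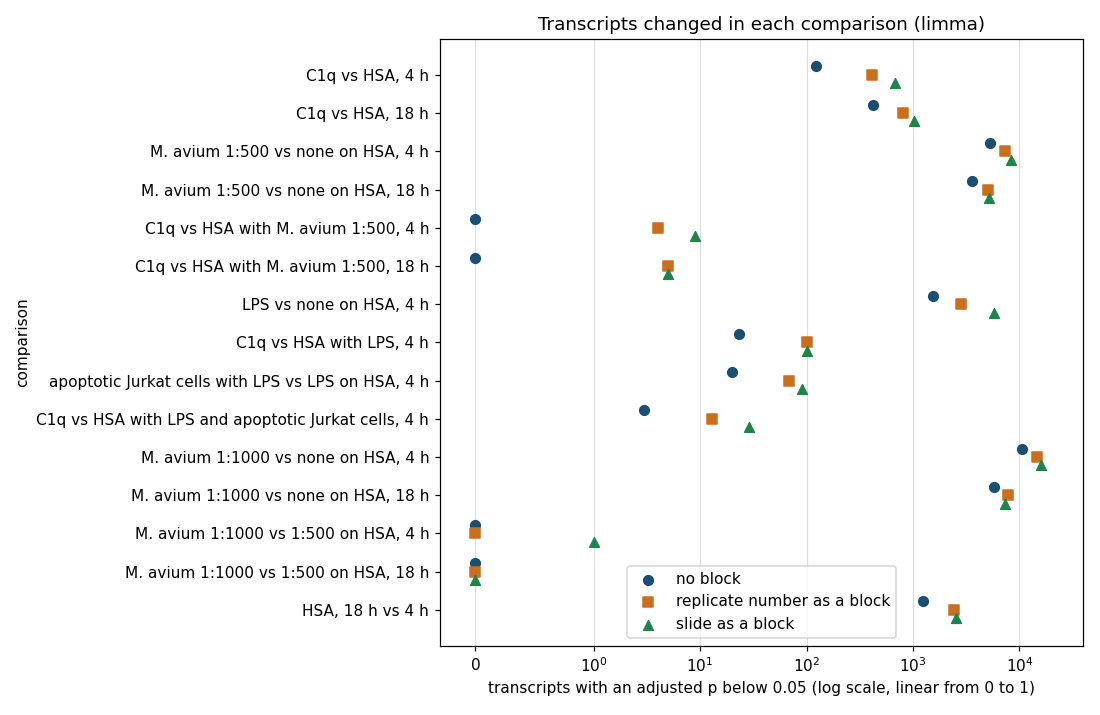
Number of transcripts with an adjusted p below 0.05 (x axis, log scale, linear from 0 to 1) in each main and secondary comparison (y axis) with no block (circles), the replicate number as a block (squares) or the slide as a block (triangles). Without a block, M. avium against no bacteria gave the largest counts, C1q without a stimulus gave 123 at 4 h and 421 at 18 h, and C1q with M. avium gave 0. With the slide as a block, LPS (5716) exceeded M. avium 1:500 at 18 h (5198).

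Between 4 h and 18 h on HSA without a stimulus, Dusp5 was 3.61-fold lower at 18 h (log2 fold change -1.85, SE 0.258, adjusted p = 1.13e-06), and the transcription factor gene Foxp4 fell by 1.68 (adjusted p = 0.00202) and the lectin receptor gene Cd33 fell by 1.59 (adjusted p = 0.0140). Rnf144b, an E3 ubiquitin ligase gene, rose at least 2.74-fold (adjusted p = 0.000733), with 1 of 5 arrays above the background level at 4 h, and Ifit3b rose by 1.72 (adjusted p = 0.0132). The myomesin gene Myom1 passed as higher (adjusted p = 0.000585), with the means of both groups below that level. All moved the same way on 3 of 3 slides. The interferon-inducible genes had a median of 0.73, with 4 rising and 6 not passing (5 when adjusted over the list alone, camera adjusted p = 3.17e-06, adjusted p = 0.161 with an estimated correlation). The signalling regulators had -0.30 with 2 falling (2 when adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.140 with an estimated correlation). Proliferation genes had 0.43 with 1 rising (3 when adjusted over the list alone, 0.00245, adjusted p = 0.176 with an estimated correlation, 0.0538 with the slide as a block). Limma called 1232 transcripts, 604 rising and 628 falling, against 2510 with the slide as a block and 261 in a fit of only these arrays, of which 80 rose. Without the outlying arrays 1467 of 2220 rose, so the balance of rises and falls depends on the arrays used. In the fit of only these arrays Ifit3b (adjusted p = 0.0527), Foxp4 (0.121) and Cd33 (0.0680) were not called. Cd33 was also not called without the arrays noted as rescanned or with background (0.0613). The count was 666 and 626 without 4 h replicates 4 and 5 and 759 without 18 h replicate 4. Ifit3b was not called without 18 h replicate 4 (adjusted p = 0.0549), nor Cd33 without 4 h replicate 5 or 18 h replicate 2 (adjusted p up to 0.104).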

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

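The patterns weighed here were picked after the data were seen, and the test of slides for the M. avium 1:1000 count was chosen only after its result was seen. Among summaries of single arrays, 13 of 70 tests found an array far from the rest of its group where chance gives 3.5, and among named genes 9 of 140 did where chance gives 7.

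Interferon-inducible genes were higher on C1q than on HSA at 18 h without a stimulus, with a median of 0.662. A difference between slides is argued against, since the lowest median within any of the 4 slides that held both groups was 0.392. A shift of dim or bright transcripts is also argued against, since 95% of random lists matched on mean level had medians from -0.193 to 0.175. Trace endotoxin in the C1q coating cannot be told apart from an effect of C1q, since transcripts that LPS raised had a median of 0.303 on C1q at 18 h (other splits up to 0.332) and those it lowered had -0.112 (other splits down to -0.193). The test was to exclude endotoxin if either median lay inside the range of the other splits, but both lie in the direction endotoxin needs and those splits mix slide differences, so that bound was wrong.

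No transcript passed between C1q and HSA with M. avium 1:500 without a block, while with the replicate number as a block 4 passed at 4 h and 5 at 18 h, and with the slide 9 and 5. A larger spread between arrays with M. avium was weighed as the reason for the 0. At 4 h the median standard deviation was 0.947 times that without (0.428 against 0.452). At 18 h it was 1.12 times that without (0.450 against 0.403), below the 1.2 set for it. These ratios decide nothing, since all groups share 1 variance estimate. For every transcript the standard error with M. avium was 1 times that without at 4 h and 1.06 times at 18 h. The number of arrays alone sets these values. A larger spread within the M. avium groups thus did not raise the standard errors, which argues against it as the reason in this fit. A smaller effect of C1q in infected cells stays open.

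More transcripts passed with M. avium at 1:1000 (10678) than at 1:500 (5277) at 4 h, while none passed between the ratios. In fits of only the arrays compared the order turned, with 2619 at 1:1000 and 2902 at 1:500. Without replicate 2 at 1:1000 the count was 6089, so a single outlying array may account for most of the excess. The count with the slide as a block was 16101 against 8381, but these counts cannot test slides as the cause, since the block raised both. The layout bears on it instead. At 4 h the HSA groups without bacteria, with 1:500 and with 1:1000 each had 1 array on the same 5 slides. A shift of a whole slide therefore cancels in both comparisons, which argues against such a shift as the cause. Whether the dose of bacteria adds to the difference stays open.

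The effect of M. avium 1:500 differed between 18 h and 4 h for 370 transcripts by an interaction test. Among named genes the difference in log2 fold change was 2.09 for Zfp811, 0.962 for Mocs1, -3.43 for Pcp4l1, -2.09 for Neil3 and -1.68 for Lnpk, and the values for Zfp811 and Neil3 rest on groups below the background level. The count was 201 without HSA M. avium 1:500 18 h replicate 3. For interferon-inducible genes the C1q effect at 18 h differed between M. avium and no stimulus by a median of -0.791, with 0 members passing and fry adjusted p = 0.0647. Only 1 slide held both M. avium groups, where the C1q effect had a median of -0.0933.

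The median log2 intensity was 7.32 in HSA with M. avium 1:500 at 4 h replicate 5, where the others of its group had 7.51 to 7.58. It was 7.44 in C1q with M. avium 1:500 at 4 h replicate 2, against 7.54 to 7.56. The upper quartile was 9.98 in HSA 18 h replicate 3 (others 10.21 to 10.25), 9.98 in C1q 18 h replicate 3 (10.21 to 10.25), 9.93 in HSA with M. avium 1:500 at 18 h replicate 3 (10.24 for the others) and 9.98 in C1q with M. avium at 18 h replicate 2 (10.16 to 10.22). The vomeronasal median was 6.045 in HSA 18 h replicate 3, against 5.05 to 5.26 in the others.

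The correlation with the rest of the group was 0.835 for HSA with M. avium 1:1000 at 4 h replicate 2 on slide 5, where the others had 0.961 to 0.978. On slide 1 it was 0.973 for HSA with LPS replicate 3, 0.945 for HSA 18 h replicate 3, 0.958 for C1q 18 h replicate 3 and 0.946 for HSA with M. avium 1:500 at 18 h replicate 3. It was 0.961 for HSA with M. avium 1:1000 at 18 h replicate 3 on slide 2.

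In single arrays Ifit1bl1 was 10.75 and Irgm2 11.68 in C1q 18 h replicate 2 (others 12.24 to 12.64 and 12.54 to 12.78). Mx1 was 9.03 in HSA 4 h replicate 1 (10.19 to 10.59). In HSA 4 h replicate 5, Cdca7l was 8.18 (9.88 to 10.19) and Gpr146 9.55 (10.27 to 10.54). In HSA with M. avium 1:500 at 18 h, Zfp811 was 8.13 in replicate 3 (9.22 to 9.41), Uhrf1 8.90 in replicate 3 (8.76 to 8.78) and Serpina3f 9.29 in replicate 1 (8.34 to 8.42). Odf3l1 was 6.47 in HSA with LPS replicate 2 (6.04 to 6.15).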

How the results depend on the processing

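Leaving out the 6 arrays with an outlying correlation to their group was chosen after the data were seen, and all other alternatives were planned. Of 99 results for single named genes, 99 kept their direction and side of the threshold with trended and robust moderation, a mean over sets, the scan day as a block and the series table, and 98 with quantile normalization. The number was 98 with the replicate number as a block, 97 with the slide as a block, 77 in fits of only the arrays compared, 86 without the arrays noted as rescanned or with background, and 89 without the outlying arrays. With the filter on dim transcripts, 94 results had a value and kept their call. Of 79 passing gene results, 61 passed in every fit without 1 array. Of 16 list results, 12 kept their call with the filter on dim transcripts. Those lost were leukocyte receptors (adjusted p = 0.206) and signalling regulators (0.0770) with M. avium 1:500 at 18 h, and signalling regulators and small nucleolar RNAs (0.0599 each) for C1q with LPS. The number was 13 with the replicate block, 14 with the slide block and 14 without the arrays noted as rescanned or with background. It was 15 each with the scan day as a block, quantile normalization and a mean over sets, and 16 without the outlying arrays and with the series table. That filter removed Apoc1, Vsig4, Tead3, Pinc and Odf3l1. Of 94 gene results between groups, 16 had no array of the lower group above the vomeronasal level of 7.24, 6 had some arrays above it and the mean below, 7 had only some arrays above it and the mean above, and 6 had the means of both groups below it (Apoc1, Vsig4, Tead3, Pinc, Odf3l1 and Myom1). For M. avium 1:500 at 4 h, C1q with M. avium at 18 h, the 1:1000 comparisons and HSA at 18 h against 4 h, the replicate numbers were not taken as pairs. Same-numbered arrays still shared a slide in 5 of 5, 1 of 4, 5 of 5 (1:1000 at 4 h), 2 of 5 (1:1000 at 18 h), 5 of 5 and 1 of 4 (between the ratios) and 3 of 5 cases, so number and slide overlap there too. The arrays that correlated best with their own number were 4 of 5, 2 of 4, 2 of 5 (1:1000 at 4 h), 1 of 5 (1:1000 at 18 h), 4 of 5 and 2 of 4 (between the ratios) and 3 of 5. Unless a cause is stated, the cause was not tested.

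With the replicate number as a block (replicate block), the counts were 415 for C1q at 4 h, 805 for C1q at 18 h, 4 for C1q with M. avium at 4 h and 5 at 18 h, 2852 for LPS, 100 for C1q with LPS, 69 for apoptotic cells, 13 for C1q with LPS and apoptotic cells and 2422 for HSA at 18 h against 4 h. They were 2 and 35 for the interaction of C1q and M. avium at 4 h and 18 h, 4 for C1q and time, 767 for M. avium and time, and 35 and 40 for C1q with 1:500 against HSA with 1:1000. The other calls it changed are given beside their results, and it changed no other call.

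With the slide as a block, the counts were 674 and 1013 for C1q at 4 h and 18 h, 8381 for M. avium 1:500 at 4 h, 9 and 5 for C1q with M. avium, 5716 for LPS, 101 for C1q with LPS, 91 for apoptotic cells, 29 for C1q with LPS and apoptotic cells, 16101 for 1:1000 at 4 h, 1 between the ratios at 4 h and 2510 for HSA at 18 h against 4 h. They were 5 and 8 for the interaction of C1q and M. avium, 5 for C1q and time, 1033 for M. avium and time, and 51 and 43 for C1q with 1:500 against HSA with 1:1000. With the scan day as a block they were 207 for C1q at 4 h, 1 for C1q with M. avium at 4 h, 51 for C1q with LPS, and 18 and 13 for C1q with 1:500 against HSA with 1:1000.

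Fits of only the arrays compared have fewer arrays to estimate the spread. They gave 6 and 120 for C1q at 4 h and 18 h, 2902 for M. avium 1:500 at 4 h, 793 for LPS, 4 for C1q with LPS, 0 for apoptotic cells, 0 for C1q with LPS and apoptotic cells, 2619 for 1:1000 at 4 h, 261 for HSA at 18 h against 4 h, 101 for M. avium and time, and 0 and 0 for C1q with 1:500 against HSA with 1:1000. The filter on dim transcripts, which tests fewer, gave 55 for C1q with LPS, 31 for apoptotic cells, and 10 and 7 for C1q with 1:500 against HSA with 1:1000. It moved the correlation across genes of the C1q effects with M. avium and with LPS at 4 h from 0.159 to 0.410. Trended and robust moderation gave 1 for the interaction of C1q and M. avium at 18 h and 1 for C1q and time. Quantile normalization gave 47 for C1q with LPS and 46 for apoptotic cells.

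Without the arrays noted as rescanned or with background, there were 191 for C1q at 18 h, 3186 for M. avium 1:500 at 4 h, 8 for C1q with LPS, 3 for apoptotic cells, 1 for C1q with LPS and apoptotic cells, 158 for M. avium and time, and 0 and 23 for C1q with 1:500 against HSA with 1:1000. The correlation of the C1q effects with M. avium and with LPS was then -0.0608, of opposite sign. Without the 6 outlying arrays there were 212 and 194 for C1q at 4 h and 18 h, 53 for C1q with LPS, 10 for apoptotic cells, 6735 for 1:1000 at 4 h, 2220 for HSA at 18 h against 4 h, 1 for C1q and time, and 0 for C1q with 1:500 against HSA with 1:1000 at 4 h.

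Leaving out each array in turn gave 59 to 155 for C1q at 4 h, 195 to 449 at 18 h, 4153 to 5551 for M. avium 1:500 at 4 h, 2808 to 3432 at 18 h, 0 to 1 for C1q with M. avium at 4 h and 0 to 1 at 18 h, 988 to 1840 for LPS and 8 to 52 for C1q with LPS. It gave 1 to 23 for apoptotic cells, 2 to 6 for C1q with LPS and apoptotic cells, 6089 to 13043 for 1:1000 at 4 h, 4733 to 5516 at 18 h and 626 to 1632 for HSA at 18 h against 4 h. Counts stayed at 0 between the ratios. For interactions it gave 0 to 1 for C1q and LPS, 0 for C1q and apoptotic cells, 0 and 0 to 2 for C1q and M. avium at 4 h and 18 h, 0 for C1q and time and 201 to 451 for M. avium and time. For C1q with 1:500 against HSA with 1:1000 it gave 0 to 18 at 4 h and 0 to 14 at 18 h. The arrays behind each large move are named beside the results they move.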

Other observations

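The tests of the transcripts that C1q changed at 4 h were chosen after those transcripts were seen, the tests that keep the pairs were chosen after the other results were seen, and the counts over other splits of the arrays were planned. The 123 transcripts called between C1q and HSA at 4 h were followed in groups that share no array with that comparison. With LPS their median change in the direction seen without a stimulus was 0.63, with 94.3% moving that way. With LPS and apoptotic cells it was 0.48 (95.1%), and with M. avium 1:500 it was 0.28 (84.6%). The highest value among 100 other splits was 0.459, 0.397 and 0.22, and 1 of 100 splits, the real one, was as large in each setting. Those splits ignore the pairs. With C1q and HSA swapped within pairs, 1 of 32 swaps, the real one, was as large in each setting (highest others 0.415, 0.342 and 0.195). This counts the side of the real value only and is the smallest share these swaps can give. Swapping every pair gives a value as large on the other side. A share under 0.05 over both sides therefore cannot be reached. Dusp5 was among these transcripts, with log2 fold changes of -1.24 with LPS, -1.11 with LPS and apoptotic cells and -0.26 with M. avium.

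A hypothesis was that C1q has a smaller effect on these transcripts with M. avium than with LPS. The difference of the medians was 0.356, inside the range of -0.470 to 0.458 that held 95% of other splits (highest 0.542). Those splits ignore the pairs and mix slides, which can widen the range. With whole pairs exchanged between LPS and M. avium, 2 of 252 divisions, the real one and its mirror, were as large (highest other 0.242). The difference lies in the direction of the hypothesis. These exchanges do not match the numbers of the pairs in the 2 settings, which mostly share slides. Of the LPS pairs, 4 of 5 lay on the same slide, so slide differences can still enter. The hypothesis is therefore not decided. Over all 43152 transcripts, which are not independent replicates, and with splits that ignore the pairs, the C1q effects at 4 h and 18 h without a stimulus correlated at 0.438 (Spearman 0.359), and 1 of 100 splits, the real one, was as large (highest other 0.382). Between 4 h without a stimulus and LPS it was 0.302 (Spearman 0.240, 5 of 100 splits, highest other 0.450), and between no stimulus and M. avium 0.287 (0.274, 7 of 100, 0.456). Between LPS and LPS with apoptotic cells it was 0.398 (0.321, 17 of 100, 0.783), and between M. avium and LPS with apoptotic cells 0.205 (0.168, 13 of 100). For M. avium at 18 h and no stimulus it was 0.174 (0.145, 29 of 100, 0.698), for M. avium and LPS 0.159 (0.115, 19 of 100, 0.558), and for no stimulus and LPS with apoptotic cells 0.127 (0.101, 30 of 100, 0.443). These 8 pairs were all that were computed.

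For each of 23 comparisons the arrays were divided in 100 ways, the real one included, and 10 comparisons had fewer than 5 divisions with as many transcripts as the real one. Of the comparisons without pairs, 1 of 100 was as large for M. avium 1:500 at 4 h (5277, highest other 4454). The same held for 1:1000 at 4 h (10678, 9895) and 18 h (5728, 2326). A random division of the arrays is argued against for these, without adjustment for the 23 comparisons. For 1:1000 at 18 h only 1 slide held both groups, so a difference between slides is not excluded. For HSA at 18 h against 4 h (1232) 2 of 100 were as large. The highest other was 1449, from a division that kept the arrays of 3 of 4 slides together, against 2510 with the slide as a block. Its groups lie partly on different slides, so it is given without a decision about chance.

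In comparisons with pairs these divisions ignore the pairs, so they are given without a decision about chance. The rule set beforehand was that with 5 or more of 100 as large, a random division could give the count. That rule was met for C1q at 4 h (8), C1q with LPS and apoptotic cells (9) and M. avium and time (8). It was also met for C1q with 1:500 against HSA with 1:1000 at 18 h (11). The rest of the paired comparisons had fewer than 5. The count was 421 for C1q at 18 h (highest other 108), 3560 for M. avium 1:500 at 18 h (2177) and 1551 for LPS (513), each with 1 of 100 as large. It was 23 for C1q with LPS (2 of 100, 39) and 20 for apoptotic cells (2 of 100, 1320), and both highest others kept the arrays of 4 of 4 slides together. It was 370 for M. avium and time, paired at 18 h (8 of 100, 3681). For C1q with 1:500 against HSA with 1:1000 it was 6 at 4 h (4 of 100, 714) and 4 at 18 h (11 of 100, 770), with 51 and 43 with the slide as a block. Both were 0 in fits of only the arrays compared, the 4 h count was 0 when any 1 of 5 arrays was left out, and its highest division kept arrays of 4 of 5 slides together. It was 123 for C1q at 4 h (8 of 100 as large, highest other 1120) and 3 for C1q with LPS and apoptotic cells (9 of 100, 4355), where the highest divisions kept arrays of 4 of 5 slides together. For C1q with LPS, apoptotic cells, C1q at 4 h and C1q with LPS and apoptotic cells, the counts with the slide as a block were 101, 91, 674 and 29, and in fits of only the arrays compared they were 4, 0, 6 and 0. Among divisions that part every pair, of which 16 exist, the highest other was 1 for C1q at 4 h, 1 at each time for C1q with 1:500 against HSA with 1:1000, 125 for LPS, and 0 for C1q at 18 h, C1q with LPS, apoptotic cells, and C1q with LPS and apoptotic cells. For M. avium 1:500 at 18 h 8 exist and the highest other was 283. These are too few for a share under 0.05. In the 9 comparisons with a real count of 0, all 100 divisions were as large, which was fixed in advance since no count is below 0. The highest others were 1 and 14 for C1q with M. avium at 4 h and 18 h, 6469 and 17 between the ratios, 899 for C1q and LPS, 3953 for C1q and apoptotic cells, 1068 and 4 for C1q and M. avium at 4 h and 18 h, and 98 for C1q and time.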
